A study of Mus musculus with 10 samples.

How the data were processed

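The authors deposited a pair of gene tables for this series, 1 for the Eed libraries (18502 genes) and 1 for the Ring1 libraries (18344 genes), both limited to protein-coding genes. Per the submitters' processing notes, reads were quantified with kallisto 0.42.5 and tested with DESeq2 3.11 on mm10, the GRCm38 mouse genome. The aligner settings and the strand marking of the library kit are not given in the sources used here, so reads from an overlapping gene on the other strand cannot be set apart. Sequencing was paired-end, from amplified total RNA. Symbols and identifiers are as in the tables; positions are from GENCODE M21, where 17830 of 18502 and 17686 of 18344 identifiers matched with their version, and 18495 and 18339 without it.

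The per-library values are normalized counts, a signal or coverage unit in the authors' deposited tables, and the text calls them normalised read counts. The log2 fold changes in the deposited tables are the authors' own. The p-value columns, raw and adjusted, are also the authors' deposited values. In every library 100% of the values were whole multiples of 1 step, within a tolerance of 1e-06, so the reads behind them could be recovered. Statements on the authors' deposited table use its values as they stand.

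The choices of groups, tests, thresholds, gene lists and named genes were made before the data were examined. limma (trend, robust) was fitted to log2(value + 1) for genes with a mean of at least 5 over the libraries of a table, each knockout against its own controls, and calls had a Benjamini-Hochberg adjusted p under 0.05. The form of test set for per-library normalized values was used. Alternatives set at the same time were no filter, a mean of at least 50, thresholds of 0.01 and 0.1, an absolute log2 fold change of at least 1, pseudocounts of 0.5 and 5, quantile normalization, centring, the authors' deposited calls, their p-values adjusted again, DESeq2 on recovered reads, 1 fit over all 10 libraries, replicate number as a block, and each library left out. Replicate numbers were shared between groups, and the column names of the Eed libraries share a letter as well. In both Ring1 groups library 2 had the fewer reads. Nothing states what the numbers or letters mark, or whether each library is a separate mouse, so the p-values measure spread between these samples. Where a group kept 1 library, its spread was assumed to be that of the other groups.

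Chosen after seeing the data were the edgeR quasi-likelihood test on recovered reads, which called 0 genes in the Eed knockout and 6 in the Ring1a/b 2KO, the Y-linked level as a term, the runs of DESeq2 without each library, Fisher's exact tests of list enrichment, and tests of 1 comparison's calls in the other. Fold changes quoted as folds are ratios of group means. For genes with 0 control reads the fold is a lower bound against a floor of 3 reads in each control library. For 1 to 3 control reads a ratio with a 95% counting interval is given. Floors and intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

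The named genes were Eed, Ring1 and Rnf2; Kitl, Edn1, Edn3, Pomc, Col2a1, Cdkn2a, Cdkn2b, Dct, Tyr and Tyrp1 for their interest in pigmentation; the 10 largest log2 fold changes in each direction among calls with a mean of at least 50 and no overlap between groups; up to 4 called members of each list with the smallest adjusted p; the 10 shared calls with the largest smaller change; and the 5 genes with the smallest adjusted p for the difference in each direction (all were 1, so ordered by unadjusted p), in both of these last cases with a mean of at least 50 in both tables. Among the largest changes, symbols of predicted genes (Gm, Rik) were skipped. After the limma calls were seen, the same rule was also applied to the calls of the authors' deposited tables. Most named genes therefore come from those tables. Edn3 was not analysed here. Epcam and Itga6 lie outside the rule and were named as sorting markers after their values were seen.

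The 31 lists, written from general knowledge, were PRC2 subunits, PRC1 subunits, Hox genes, non-Hox developmental regulators, cell cycle inhibitors, factors acting on melanocytes, melanocyte markers, collagens, laminins and other matrix genes, Wnt ligands and pathway genes, Merkel cell markers, basal keratinocyte genes, keratinocyte differentiation genes, stress and wound keratinocyte genes, hair follicle genes, sebaceous gland genes, Langerhans and other myeloid markers, T cell markers, fibroblast markers, endothelial markers, muscle and adipocyte markers, Schwann cell and neuronal markers, red blood cell genes, proliferation genes, p53 target genes, interferon response genes, immediate early and heat shock genes, germline genes, imprinted genes, mitochondrially encoded genes and sex-linked marker genes. Each was tested with camera at a preset correlation of 0.01, with an estimated correlation and by ranks, adjusted over the lists. For 62 of 62 list medians, setting genes with 0 control reads at their bound gave the same median.

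In a self-test, reads were simulated with known changes. limma recovered 28%, 80%, 100% and 100% of changes of 2-, 4-, 8- and 16-fold in the Eed design and 10%, 84%, 96% and 98% in the Ring1 design, with 12 of 177 and 25 of 179 calls on unchanged genes. edgeR made 174 and 192 calls, 9 and 32 of them on unchanged genes, and DESeq2 made 245 and 217, with 56 and 47. The interaction test found 93% of 100 genes changed 8- or 16-fold. These rates hold for the simulated reads only. In the Eed libraries limma did not call Gria3, 72.4-fold higher (adjusted p = 0.235), or Pitx1, 86.8-fold higher (adjusted p = 0.717). The rise of Pitx1 was uneven, with counts of 442, 58.1 and 10.3 in the knockouts. The absence of limma calls in the Eed knockout thus does not exclude large changes. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.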

Results

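The data are RNA sequencing read counts from sorted mouse skin cells that lack a subunit of either Polycomb complex. Polycomb repressive complexes 1 and 2 (PRC1 and PRC2) hold developmental genes silent through histone marks, and the series title names their role in skin pigmentation. Eed is a core subunit of PRC2. Ring1 (Ring1a) and Rnf2 (Ring1b) are the ubiquitin ligase subunits of PRC1. The cells came from back-skin epidermis between the hair follicles at postnatal day 71 and were sorted for EpCAM, Sca1 and high α6-integrin, a surface profile of basal keratinocytes. Recombination was induced with 20 mg/ml 4-hydroxytamoxifen, 100 µl a day on the skin for 4 days from postnatal day 50. The 10 libraries form 4 groups: Eed control (n = 3), Eed knockout (n = 3), Ring1 control (n = 2) and Ring1a/b 2KO, which lacks both Ring1 genes (n = 2). Each knockout has its own controls, and the 2 deposited tables were normalized separately, so levels were tested only within a table.

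The reads recovered from the normalized values numbered 34607227, 39006853 and 32667439 in Eed controls 1 to 3 and 31699979, 32642691 and 40701183 in Eed knockouts 1 to 3. Ring1 controls 1 and 2 held 25158144 and 7162907 reads, and Ring1a/b 2KO libraries 1 and 2 held 19814853 and 6237389. Mitochondrially encoded genes took 2.34%, 2.81% and 2.51% of reads in the Eed controls and 3.31%, 3.58% and 2.85% in the Eed knockouts. They took 6.51% and 7.28% in the Ring1 controls and 8.16% and 12.7% in the Ring1a/b 2KO libraries.

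The targeted genes were measured first. Eed (ENSMUSG00000030619.9, mm10 chromosome 7, 89954654 to 89980983, whole gene) had a normalised read count of 1623 ± 272 (SD, n = 3) in Eed controls and 1298 ± 139 (SD, n = 3) in Eed knockouts. Its log2 fold change was −0.31 (SE 0.197, limma adjusted p = 0.989). Ring1 (ENSMUSG00000024325.8, chromosome 17, 34020792 to 34024680) had counts of 66.2 and 211 in the Ring1 controls and 104 and 115 in the 2KO libraries, a log2 fold change of −0.11 (SE 0.543, limma adjusted p = 0.962). Rnf2 (ENSMUSG00000026484.13, chromosome 1, 151458004 to 151500955) had 672 ± 3.45 (SD, n = 2) in controls and 624 ± 135 (SD, n = 2) in 2KO libraries, a log2 fold change of −0.12 (SE 0.23, limma adjusted p = 0.889). The floxed exons are not given in the sources used here, so counts summed over the whole gene cannot check the labels.

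The Eed comparison asks which genes of these epidermal cells depend on PRC2. Developmental regulators other than Hox genes, transcription factors that pattern the embryo, rose as a group in the Eed knockout: 71 of 85 tested members had a positive log2 fold change, with a median of 0.92 (camera adjusted p = 4.06e-14, and adjusted p = 0.391 with an estimated correlation). Genes of keratinocyte differentiation, which build the outer layers, fell as a group, with 31 of 36 members negative and a median of −0.61 (camera adjusted p = 3.04e-07, and adjusted p = 0.391 with an estimated correlation). Among single genes, Gria3, a glutamate receptor subunit (ENSMUSG00000001986.16, chromosome X, 41400854 to 41678601), had counts of 11.7, 7.10 and 25.3 in the controls and 782, 285 and 2122 in the knockouts, 72.4-fold. Col2a1, the main collagen of cartilage (ENSMUSG00000022483.17, chromosome 15, 97975602 to 98004695), had 0.649 ± 1.12 in controls and 141 ± 122 in knockouts (SD, n = 3). Its ratio of reads was 236 (95% counting interval 65 to 1950). The median of the developmental regulators was 0.44 without knockout 1 and 1.58 without knockout 3, and that of the differentiation genes was −0.37 without control 3 and −0.39 without knockout 1.

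limma called 0 of 16122 genes at an adjusted p under 0.05, with 762 genes at an unadjusted p under 0.05, 548 of them higher, and a smallest adjusted p of 0.235. edgeR on the recovered reads called 0 of 15081, with 698 at an unadjusted p under 0.05. Both unadjusted counts lie under the share of 0.05 that chance alone would give. Another split of the Eed libraries into 3 and 3 gave limma 2896 such genes. The authors' deposited table, made with DESeq2, called 127 of 16684 genes, 118 higher and 9 lower, and DESeq2 on the recovered reads also called 127. Of those calls, the values of the groups did not overlap for 111 of the 118 higher genes and for 9 of the 9 lower genes. Over all genes, 9.2% showed no overlap, where chance gives 10% for 3 against 3. The control mean was under 10 for 47 of the 118. The limma count was 2 without control 2 and 4 without knockout 2. The DESeq2 count was 50 without control 1, 81 without control 3 and 30 without knockout 1.

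Among the developmental regulators the authors' deposited table called 11 members higher and 0 lower. Tbx3, a T-box factor of limb and mammary development, had 2.66 ± 0.551 in controls and 105 ± 84.2 in knockouts (SD, n = 3), 39.5-fold. Isl1, a factor of motor neurons and heart progenitors, went from 4.69 ± 2.97 to 113 ± 82.2, 24.1-fold, and Zic1, a neural factor, from 14.6 ± 4.68 to 196 ± 181, 13.4-fold. Sim2 had a ratio of 288 (95% counting interval 51.3 to 11400). Its counts were 260, 41.5 and 29.2 in knockouts 1 to 3, so knockout 1 carried most of that ratio. In the authors' deposited table the log2 fold changes were 5.30 for Tbx3 (adjusted p = 5.31e-06), 4.59 for Isl1 (adjusted p = 2.59e-05) and 3.74 for Zic1 (adjusted p = 8.19e-05). Adjusted over the list alone, limma called 10 of the 85. The calls were enriched among these regulators (Fisher's exact test, two-sided, adjusted p = 2.03e-09).

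Hox genes, which set position along the body axis, rose as a group, with 22 of 33 tested members positive and a median of 0.38 (camera adjusted p = 0.000855, and adjusted p = 0.558 with an estimated correlation). The group call was lost without knockout 2 (median 0.093, adjusted p = 0.129), and the median was 0.23 without control 3, 0.12 without knockout 1 and 0.59 without knockout 3. The authors' deposited table called 4 Hox genes higher, with adjusted p = 0.000116 for Hoxd10, 0.000176 for Hoxd11, 0.00705 for Hoxc10 and 0.0204 for Hoxd9. Hoxd10 had 0 reads in the 3 controls and 47.5 ± 37.0 in knockouts (SD, n = 3), at least 15.8-fold higher. Hoxc10 was at least 12.2-fold higher by the same floor. Knockout 1 carried most of that rise, with Hoxc10 counts of 99.5, 5.19 and 5.52 in knockouts 1 to 3. Hoxd9 went from 7.68 ± 5.78 to 83.2 ± 61.5, 10.8-fold. Adjusted over the list alone, limma called 2 Hox genes. The called genes were enriched in the list (Fisher's exact test, two-sided, adjusted p = 0.00163). That test, here and for the other lists, counts genes as independent. Of the called Hox genes, Hoxd9, Hoxd10 and Hoxd11 are neighbours on chromosome 2.

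Among the genes chosen for pigmentation, Kitl, the melanocyte growth factor made by keratinocytes (chromosome 10, 100015630 to 100100416), had 503 ± 173 in controls and 941 ± 281 in knockouts (SD, n = 3), 1.87-fold. Its limma log2 fold change was 0.92 (SE 0.313, adjusted p = 0.912). Edn1, another factor that acts on melanocytes, had a limma log2 fold change of 0.76 (adjusted p = 0.989), and Pomc, the precursor of melanocyte-stimulating hormone, had −0.31 (adjusted p = 0.989). The 36 tested factors acting on melanocytes had a median of 0.085 (camera adjusted p = 0.244), with Col2a1 the 1 member called in the authors' deposited table (adjusted p = 1.11e-06). Melanocyte markers rose as a group, 10 of 14 positive with a median of 0.26 (camera adjusted p = 0.0479, and adjusted p = 0.391 with an estimated correlation). The call was lost without any 1 of control 1, control 2, control 3, knockout 2 or knockout 3 (adjusted p of 0.0547, 0.223, 0.0537, 0.0824 and 0.353), and the median was 0.48 without control 1 and 0.16 without knockout 3. Mlana, a melanosome protein, had 0 reads in the controls and 32.5 ± 22.2 in knockouts, at least 10.8-fold higher. The pigment enzyme Dct had 57.0 ± 20.8 and 56.9 ± 14.7, and Tyr, the rate-limiting enzyme of melanin synthesis, had 57.0 ± 10.3 and 42.4 ± 8.99. Tyrp1, another enzyme of the pathway, had 1.62 ± 2.81 and 10.5 ± 13.1. The cell cycle inhibitors had a median of 0.41 over 7 members (camera adjusted p = 0.467). Cdkn2a, a known Polycomb target, had a ratio of 32.8 (95% counting interval 8.73 to 276, limma adjusted p = 0.989). Its counts were 60.0, 17.6 and 0 in knockouts 1 to 3, so the ratio rests mostly on knockout 1. Cdkn2b had a log2 fold change of 0.91 (limma adjusted p = 0.989).

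Keratinocyte programmes also differed. Among the differentiation genes, Krt2 went against the group and was 8.68-fold higher, at 113 ± 62.5 and 983 ± 936 (SD, n = 3). Stress and wound genes rose, 15 of 22 positive with a median of 0.72 (camera adjusted p = 0.00317, and adjusted p = 0.558 with an estimated correlation), a call lost without control 2 (adjusted p = 0.245) or knockout 1 (adjusted p = 0.0919). The stress median was 1.16 without control 3 and 1.34 without knockout 2. Krt6a, a keratin of wounded epidermis, went from 1261 ± 419 to 15355 ± 16481, 12.2-fold, with 34323 in knockout 1. Krt6a and the cystatin gene Stfa3 share sequence with near-identical relatives, so their counts are uncertain. Hair follicle genes rose, 15 of 23 positive with a median of 0.70 (camera adjusted p = 0.00061, and adjusted p = 0.391 with an estimated correlation); Krt27 of the inner root sheath went from 4.72 ± 4.56 to 57.7 ± 49.9, and the median was 0.37 without knockout 1. Basal keratinocyte genes had a median of −0.13 (camera adjusted p = 0.0867). The sorting marker Epcam stayed at 4482 ± 1063 and 4507 ± 1215.

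Laminins and other matrix genes rose, 21 of 29 positive with a median of 0.31 (camera adjusted p = 0.000254, and adjusted p = 0.391 with an estimated correlation), and of 0.19 without knockout 1. Dcn, a matrix proteoglycan, went from 42.9 ± 28.6 to 433 ± 383 (SD, n = 3), 10.1-fold. Wnt ligands and pathway genes rose, 25 of 42 positive with a median of 0.16 (camera adjusted p = 0.00718, and adjusted p = 0.406 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0682) or knockout 3 (adjusted p = 0.0614). The Wnt median was 0.285 without control 2 and 0.077 without knockout 1. The Wnt gene Sfrp2, a secreted Wnt modulator, had 0 control reads and was at least 10.2-fold higher. Its counts were 65.9, 24.9 and 0.789 in knockouts 1 to 3, so the bound rests mostly on knockout 1. Collagens had a median of 0.13 (camera adjusted p = 0.333), with Col5a1 5.2-fold higher. Proliferation genes rose, 24 of 25 positive with a median of 0.34 (camera adjusted p = 0.00061, and adjusted p = 0.601 with an estimated correlation), but without knockout 1 their median was 0.007 (adjusted p = 0.871), without control 1 it was 0.21 and without knockout 3 it was 0.58. Targets of p53 rose, 15 of 22 positive with a median of 0.235 (camera adjusted p = 0.00583, and adjusted p = 0.558 with an estimated correlation), a call lost without knockout 3 (median 0.055, adjusted p = 0.791), and the median was 0.39 without knockout 2. Their member Ccng1 went from 2733 ± 450.5 to 5491 ± 1459.

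Immediate early and heat shock genes, which respond to handling of tissue, fell, 23 of 26 negative with a median of −0.32 (camera adjusted p = 8.78e-06, and adjusted p = 0.391 with an estimated correlation). Mitochondrially encoded genes rose, 11 of 13 positive with a median of 0.34 (camera adjusted p = 0.012, and adjusted p = 0.558 with an estimated correlation), a call lost without control 1 (median 0.22, adjusted p = 0.211) or knockout 2 (adjusted p = 0.245), and the median was 0.21 without knockout 1. Red blood cell genes fell by a median of −1.12 over 4 members (camera adjusted p = 0.0349, and adjusted p = 0.558 with an estimated correlation), a call lost without control 2 (median −0.65, adjusted p = 0.442), knockout 1 (median −0.59, adjusted p = 0.239) or knockout 3 (adjusted p = 0.147), with a median of −2.10 without knockout 2. The Y-linked markers, which differed between libraries within each group, had a median of −2.11 over 4 members (camera adjusted p = 0.0435, and adjusted p = 0.558 with an estimated correlation). That call was lost without control 1, control 2, knockout 1 or knockout 3 (adjusted p of 0.213, 0.402, 0.535 and 0.255), and the median was −1.05, −1.34, −3.89, −0.77 and −4.14 without controls 1, 2 and 3 and knockouts 1 and 2. High and low levels occurred in both groups: the summed counts of Ddx3y and Eif2s3y were 5804, 4058 and 25.3 in controls 1 to 3 and 14.4, 4743 and 26.8 in knockouts 1 to 3.

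The other lists did not pass. Medians and camera adjusted p were 0.009 and 0.936 for PRC2 subunits, and 0.018 and 0.467 for PRC1 subunits. The PRC1 subunit Bmi1 went from 359 ± 38.3 to 746 ± 180.4 (SD, n = 3). Markers of other cells gave 0.54 and 0.357 for Merkel cells, −0.041 and 0.982 for Langerhans and other myeloid cells, −0.39 and 0.403 for T cells, and 0.385 and 0.267 for fibroblasts. Endothelial markers gave −0.045 and 0.492, muscle and adipocyte markers −0.23 and 0.763, Schwann cell and neuronal markers −0.21 and 0.982, and sebaceous gland genes −0.28 and 0.467. Interferon response genes gave −0.11 and 0.487, germline genes 0.53 and 0.48, and imprinted genes 0.19 and 0.0921. Leaving out 1 library gave a call for basal keratinocyte genes (without control 3, adjusted p = 0.0323), imprinted genes (without knockout 1, 0.0235), interferon response genes (without control 1, 0.00256) and Langerhans and other myeloid markers (without control 3, 0.0161). The mean and the median differed in sign for sebaceous, Langerhans and other myeloid, muscle and adipocyte, Schwann cell and interferon lists. Of 31 lists, 14 passed camera with the preset correlation, 11 by ranks and 0 with an estimated correlation, and the count was 9 without knockout 3. limma called 0 members of any list over all genes; adjusted over the list alone it called 3 p53 targets and 1 higher gene each in the stress, melanocyte marker, melanocyte factor, collagen, laminin, Merkel, fibroblast and Schwann lists, and 1 lower endothelial marker.

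The largest authors' calls outside these groups included Igfbp2, a carrier of insulin-like growth factors, at 25.6 ± 20.5 in controls and 1197 ± 1360.2 in knockouts (n = 3), and Susd4, a complement regulator, at 4.71 ± 4.71 and 149.8 ± 65.1. In the authors' deposited table Igfbp2 had a log2 fold change of 5.55 (adjusted p = 0.00202), Gria3 had 6.18 (adjusted p = 8.64e-18), and the adjusted p of Susd4 was 1.02e-08. Of the 9 lower genes, Kctd12, an auxiliary subunit of GABA-B receptors, had 1369 ± 295 in controls and 657 ± 80.1 in knockouts, and the nuclease gene Dnase1l3 had 1314 ± 434 and 410.1 ± 191. Their log2 fold changes in the authors' deposited table were −1.06 (adjusted p = 0.00958) and −1.68 (adjusted p = 0.00996).

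**Figure D1:**
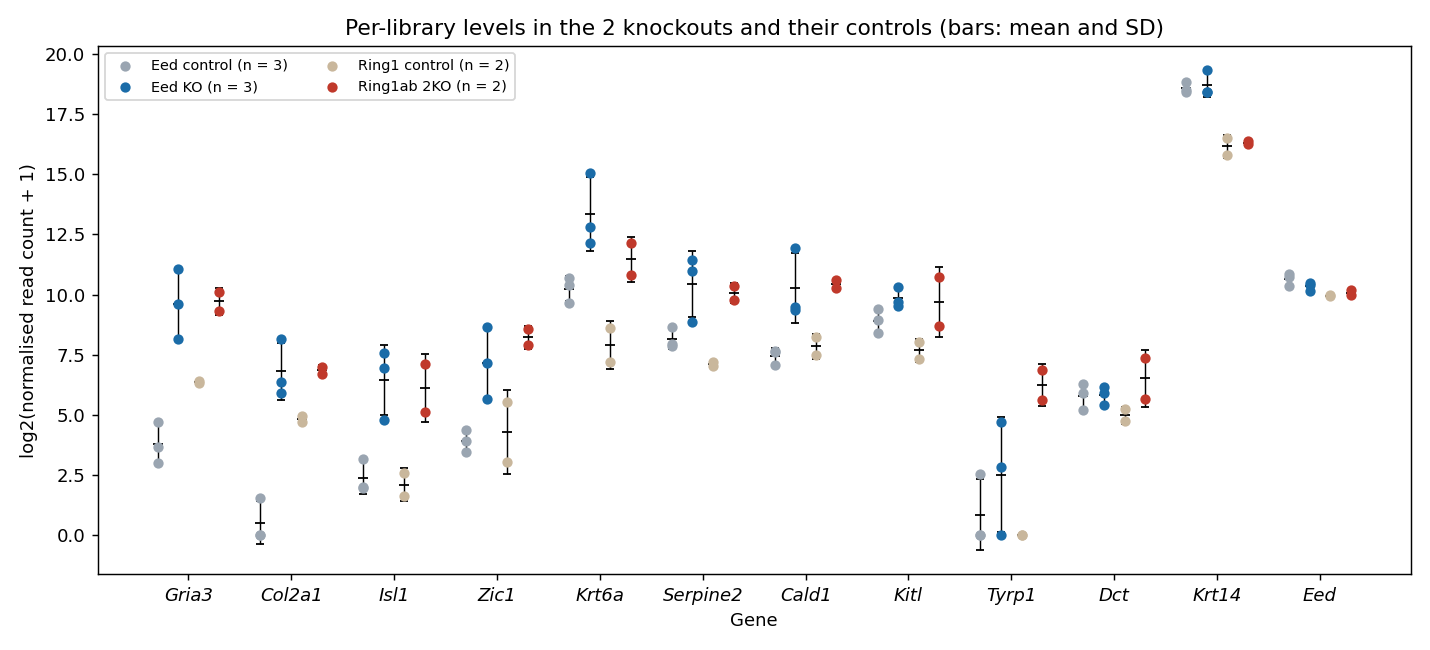
Normalised read counts of 12 genes, as log2(count + 1), in each library of the 4 groups, with bars for the mean and SD. Gria3 lies between 285 and 2122 in the Eed knockouts against 7.10 to 25.3 in their controls, while Dct has nearly equal means of 57.0 and 56.9.

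The Ring1 comparison asks which genes depend on the catalytic subunits of PRC1. Developmental regulators other than Hox genes rose in the Ring1a/b 2KO, with 75 of 86 tested members positive and a median log2 fold change of 1.66 (camera adjusted p = 8.77e-18, and adjusted p = 0.305 with an estimated correlation). Stress and wound genes of keratinocytes rose, 14 of 19 positive with a median of 2.60 (camera adjusted p = 2.67e-06, and adjusted p = 0.413 with an estimated correlation). Differentiation genes fell, 27 of 36 negative with a median of −0.76 (camera adjusted p = 0.000256, and adjusted p = 0.553 with an estimated correlation). Serpine2, a serine protease inhibitor, rose from 138 ± 9.20 to 1096 ± 322 (SD, n = 2), 7.95-fold. Tyrp1, a melanin synthesis enzyme (chromosome 4, 80834123 to 80851719), had 0 reads in the controls and counts of 116 and 48.4 in the 2KO libraries, at least 25-fold higher. The call of the differentiation genes was lost without control 1 (median −0.22, adjusted p = 0.22), and their median was −1.27 without control 2 and −0.35 without 2KO 2. The stress median was 1.52 without 2KO 2.

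limma called 6 of 15310 genes, with 1597 at an unadjusted p under 0.05. Those that rose were Serpine2 (log2 fold change 2.95, SE 0.27, adjusted p = 0.00886), the defensin gene Defb1 (2.72, SE 0.247, adjusted p = 0.00886), Gria3 (3.36, SE 0.318, adjusted p = 0.00886), the adhesion gene Ncam1 (3.72, SE 0.388, adjusted p = 0.0152) and Cald1, an actin regulator (2.59, SE 0.283, adjusted p = 0.0221). Y-linked Uty fell by −3.36 (SE 0.418, adjusted p = 0.0436). Each had both 2KO libraries beyond both controls, and Ncam1 went from 43.3 ± 4.54 to 614 ± 281 and Cald1 from 237 ± 85.1 to 1395 ± 217 (SD, n = 2). edgeR on the recovered reads also called 6, of 14565. The authors' deposited table called 231 of 15498 genes, 183 higher and 48 lower, and DESeq2 on the recovered reads gave the same number. Their groups did not overlap for any of the 231, as for 42.9% of all genes where chance gives 33.3% for 2 against 2, and the control mean was under 10 for 46 of the 183. The limma count was 0 without control 1 (smallest adjusted p of the 6 genes 0.458), 0 without control 2 (0.391), 565 without 2KO 1, of which 433 were lower, and 13 without 2KO 2. The DESeq2 count was 39, 95, 679 and 93 in that order, and the excess of higher calls turned without 2KO 1 (178 higher, 501 lower) and with the replicate number as a block (152 higher, 168 lower).

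Among the developmental regulators the authors' deposited table called 13 higher and 0 lower. Ebf3, a neurogenic factor, had 27.6 ± 24.4 in controls and 347 ± 18.4 in 2KO libraries (SD, n = 2), Tbx15 had 24.1 ± 3.51 and 226 ± 104, and Zic1 had 26.1 ± 26.6 and 308 ± 101. In the authors' deposited table their log2 fold changes were 3.76 (adjusted p = 3.97e-07), 3.22 (adjusted p = 1.25e-06) and 3.66 (adjusted p = 8.14e-05). Adjusted over the list alone, limma called 28 of them, and the authors' calls were enriched in the list (Fisher's exact test, two-sided, adjusted p = 1.3e-09). Hox genes rose, 23 of 35 positive with a median of 0.50 (camera adjusted p = 0.00211, and adjusted p = 0.541 with an estimated correlation), a call lost without control 1 (median 0.25, adjusted p = 0.0792), with a median of 0.20 without 2KO 2. Hoxd13 went from 32.4 ± 22.3 to 266 ± 55.6, 8.19-fold. The authors' deposited table gave an adjusted p of 1.61e-05 for Hoxd13 and of 0.00893 for Hoxa10, whose log2 fold change was 2.32. Over the list alone limma called 5 Hox genes, and the authors' calls were enriched (Fisher's exact test, two-sided, adjusted p = 0.00459).

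Melanocyte markers rose as a group, 14 of 16 positive with a median of 1.29 (camera adjusted p = 3.83e-06, and adjusted p = 0.413 with an estimated correlation), and of 0.855 without control 1 and 0.67 without 2KO 1. The authors' deposited table called Tyrp1 (adjusted p = 3.48e-05) and Pax3 (log2 fold change 2.32, adjusted p = 0.0391), a regulator of the pigment lineage. limma gave Tyrp1 an adjusted p of 0.128. Dct had 31.0 ± 7.80 in controls and 107 ± 79.9 in 2KO libraries (SD, n = 2), 3.44-fold, and a limma log2 fold change of 1.54 (adjusted p = 0.445), and Tyr had 1.21 (adjusted p = 0.563). Kitl had counts of 259.9 and 161 in controls and 409 and 1676 in 2KO libraries, a limma log2 fold change of 2.01 (SE 0.856, adjusted p = 0.56); without 2KO 1 it was 3.03 (adjusted p = 0.00243) and without 2KO 2 it was 0.996 (adjusted p = 0.817). The 33 factors acting on melanocytes had a median of 0.059 (camera adjusted p = 0.881), and Edn1 had a log2 fold change of 0.25 (limma adjusted p = 0.887). Col2a1 had 27.5 ± 3.47 and 116 ± 16.6, 4.21-fold, with limma adjusted p = 0.207 and adjusted p = 0.0125 in the authors' deposited table. Pomc, at 3.27 ± 2.42 and 2.41 ± 1.66, and Cdkn2a, at 2.34 ± 3.32 and 4.30 ± 3.54, lay below the filter. Cdkn2b had a log2 fold change of 1.33 (limma adjusted p = 0.399), and the 6 cell cycle inhibitors a median of 0.13 (camera adjusted p = 0.454). Merkel cell markers, of the touch-sensing cells of the epidermis, rose, 7 of 7 positive with a median of 1.44 (camera adjusted p = 0.00173, and adjusted p = 0.418 with an estimated correlation), and of 0.82 without control 1. Their members Isl1 and Krt18 had 3.53 ± 2.05 and 85.7 ± 74.0, and 4.27 ± 1.33 and 64.3 ± 45.4. The list median was that of Chga, with counts of 10.4 and 0 in controls and 7.42 and 8.97 in 2KO libraries. Its groups overlapped, as did those of Insm1, Syp and Rab3c, while those of Isl1, Krt18 and Piezo2 did not.

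Among the stress and wound genes, Krt6a went from 268 ± 171 to 3126 ± 1893 (SD, n = 2), 11.7-fold, Stfa3 from 1560.2 ± 247 to 13692 ± 8778, 8.78-fold, and S100a8, an alarm protein of injured epidermis, from 6.45 ± 0.280 to 107 ± 117. Hair follicle genes rose, 15 of 21 positive with a median of 1.03 (camera adjusted p = 0.000932, and adjusted p = 0.418 with an estimated correlation), a call lost without 2KO 1 (median 0.35, adjusted p = 0.0912), with a median of 0.61 without control 1 and 0.69 without 2KO 2. The follicle bulge gene Cd34 went from 17.4 ± 3.42 to 133 ± 88.4, and Lhx2, a factor of follicle stem cells, from 117 ± 0.622 to 376 ± 158. Among the differentiation genes, Flg2 and Lor of the cornified layer had 654 ± 245 and 83.6 ± 52.3, and 528 ± 321 and 116 ± 60.8, while Krt1 of the layer above the basal cells was 2.53-fold higher, at 11907 ± 2886 and 30077 ± 8271. Basal keratinocyte genes fell, 14 of 16 negative with a median of −0.50 (camera adjusted p = 9.18e-05, and adjusted p = 0.541 with an estimated correlation). The sorting marker Itga6 (α6-integrin) had 15381 ± 2714 and 9541 ± 279, a log2 fold change of −0.68 (limma adjusted p = 0.372).

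Imprinted genes, expressed from 1 parental copy, rose, 19 of 23 positive with a median of 0.79 (camera adjusted p = 2.31e-05, and adjusted p = 0.418 with an estimated correlation), and of 0.33 without control 1 and 0.52 without 2KO 2. Igf2, a fetal growth factor, went from 627 ± 153 to 3247 ± 2233 (SD, n = 2), 5.18-fold, and Plagl1, a growth regulator, from 249 ± 18.0 to 657 ± 109.9. Proliferation genes rose, 24 of 25 positive with a median of 0.47 (camera adjusted p = 2.49e-07, and adjusted p = 0.553 with an estimated correlation), and of 0.70 without 2KO 1 and 0.23 without 2KO 2. Targets of p53 rose, 15 of 22 positive with a median of 0.38 (camera adjusted p = 0.00391, and adjusted p = 0.501 with an estimated correlation), a call lost without control 2 (adjusted p = 0.201). Mitochondrially encoded genes rose, 13 of 13 positive with a median of 0.42 (camera adjusted p = 0.00174, and adjusted p = 0.554 with an estimated correlation), and of 0.26 without 2KO 2. Immediate early and heat shock genes fell, 25 of 26 negative with a median of −1.09 (camera adjusted p = 0.000259, and adjusted p = 0.612 with an estimated correlation). That call was lost without control 1 (median −0.385, adjusted p = 0.0901), and without 2KO 2 the median was 0.215 (adjusted p = 0.163); it was −1.82 without control 2 and −2.44 without 2KO 1. Y-linked markers fell, 4 of 4 negative with a median of −4.26 (camera adjusted p = 1.32e-08, and adjusted p = 0.418 with an estimated correlation). Ddx3y and Eif2s3y summed to 1665 and 629.8 in the controls and 9.27 and 50.2 in the 2KO libraries, so this difference runs with the genotype.

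The authors' deposited table also called lower the growth factor gene Ereg, the Wnt amplifier Rspo3 and the basement membrane gene Lama1, with log2 fold changes of −2.62 (adjusted p = 0.00166), −2.35 (adjusted p = 0.000858) and −1.55 (adjusted p = 0.00126). Lama1 had 889 ± 155 and 301 ± 93.5 and Rspo3 289 ± 38.0 and 54.8 ± 34.4 (SD, n = 2). The laminin and matrix list as a whole had a median of −0.096 (camera adjusted p = 0.772), with a mean of the opposite sign, and the collagens had 0.045 (adjusted p = 0.454). For the remaining lists the medians and camera adjusted p were 0.031 and 0.881 for PRC2 subunits, −0.13 and 0.312 for PRC1 subunits, 0.19 and 0.521 for Wnt genes, and 0.008 and 0.993 for sebaceous gland genes. Langerhans and other myeloid markers gave −0.885 and 0.265, T cell markers 0.34 and 0.51, fibroblast markers 0.33 and 0.172, endothelial markers 0.59 and 0.327, and muscle and adipocyte markers 0.87 and 0.169. Schwann cell and neuronal markers gave −0.83 and 0.172, and germline genes 0.24 and 0.269. The mean also differed in sign from the median for melanocyte factors and Schwann cell markers. Leaving out 2KO 2 gave a call for Schwann cell and neuronal markers (adjusted p = 0.0293). Interferon response genes had −0.47 and 0.253, with −1.37 (adjusted p = 5.73e-05) without 2KO 1 and 0.385 (adjusted p = 0.0022) without 2KO 2. Red blood cell genes had 2 measured members, too few to test, with a median of −0.35. Of 30 lists tested, 14 passed with the preset correlation, 14 by ranks and 0 with an estimated correlation. limma called 1 list member over all genes, Uty. Adjusted over the list alone it called 8 stress genes, 4 hair follicle genes, 4 imprinted genes, 3 Wnt genes, 2 Merkel markers, 2 melanocyte factors and 1 each of the melanocyte, fibroblast, p53 and mitochondrial lists higher. It called 6 basal genes, 4 Y-linked markers, 2 Schwann cell and neuronal markers and 1 Wnt gene lower, 6 matrix genes higher with 4 lower, 2 collagens higher with 3 lower, and 1 differentiation gene in each direction.

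**Figure D2:**
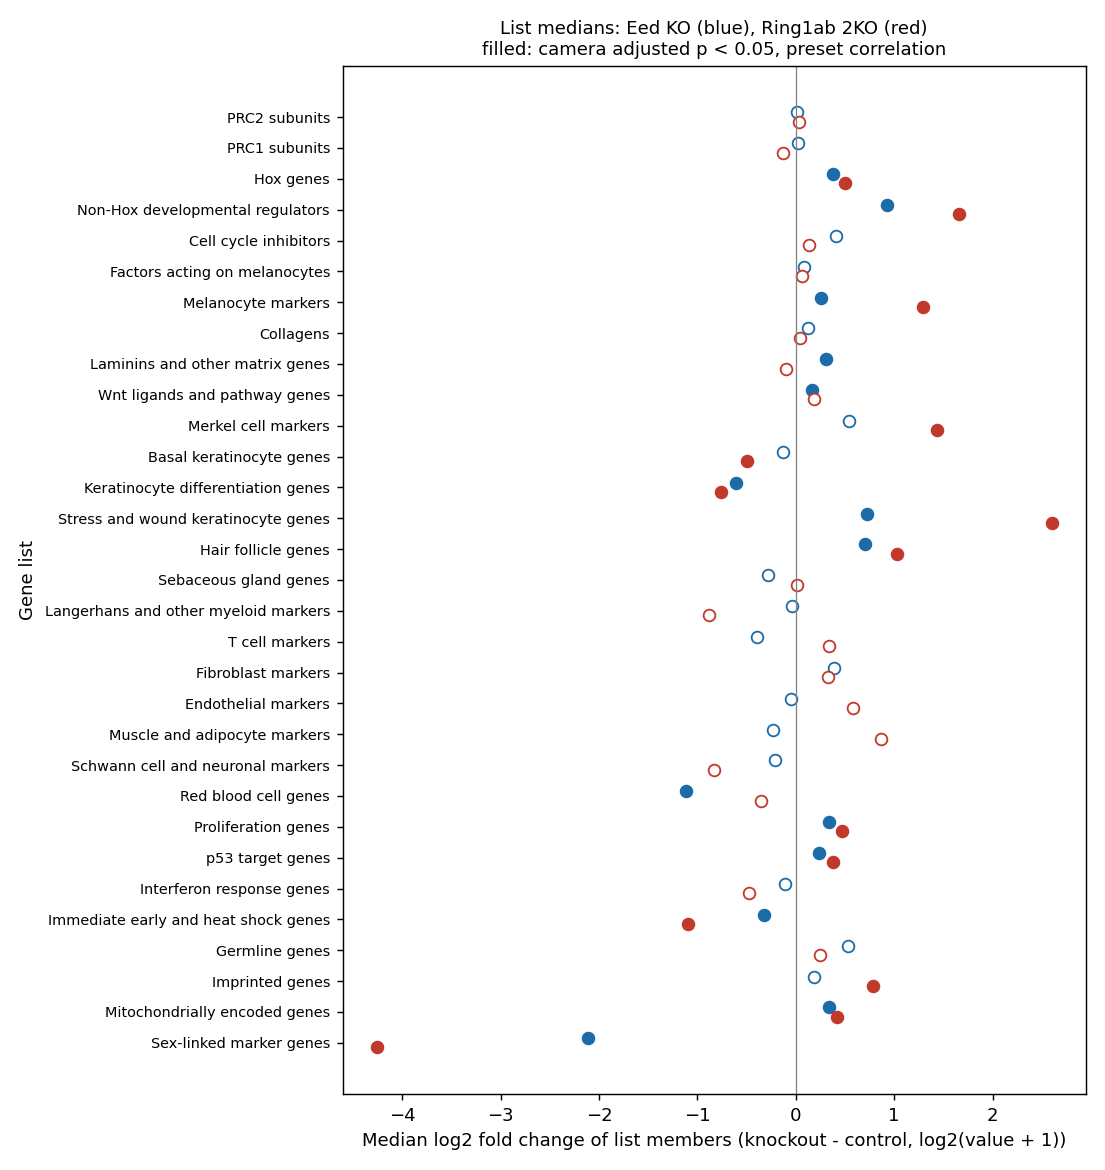
Median log2 fold change of each of the 31 gene lists in the Eed knockout (blue) and the Ring1a/b 2KO (red), filled where camera gave an adjusted p under 0.05 with the preset correlation. Developmental regulators lie at 0.92 and 1.66, and differentiation genes at −0.61 and −0.76.

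Whether loss of either complex changes the same genes was tested on the 15352 genes with an adjusted p in both tables of the authors. Gria3, the neural factor Zic1, Isl1, Igfbp2 and the wound keratin Krt6a were among 47 genes called higher in both, where 1.26 were expected by chance (114 and 170 calls, Fisher's exact test, two-sided, p = 1.81e-63). Kctd12 was the 1 gene called lower in both (0.025 expected, Fisher's exact test, two-sided, p = 0.0247), and 0 genes were called in opposite directions. In the authors' deposited tables the log2 fold changes in the Eed knockout and the Ring1a/b 2KO were 3.74 and 3.66 for Zic1, 4.59 and 4.75 for Isl1, 5.55 and 4.07 for Igfbp2, 3.61 and 3.55 for Krt6a, and −1.06 and −1.81 for Kctd12. Pitx1, which specifies hindlimb, had 6.43 and 3.08, and Dhh, a hedgehog ligand, had 2.90 and 3.29. By limma no gene was shared, since it called 0 genes in the Eed knockout and 6 in the 2KO. At an unadjusted p under 0.05 it had 762 and 1597 genes, of which the 762 are no more than chance would give. Across 15096 genes the limma log2 fold changes had Pearson r = 0.486 and Spearman rho = 0.433, with 67% in the same direction; genes are not independent replicates. The DESeq2 count of 48 shared calls was 22, 28 and 15 without Eed control 1, Eed control 3 or Eed knockout 1, and 11, 23 and 15 without Ring1 control 1, Ring1 control 2 or 2KO 2; the limma count was 2 without Eed knockout 2.

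**Figure D3:**
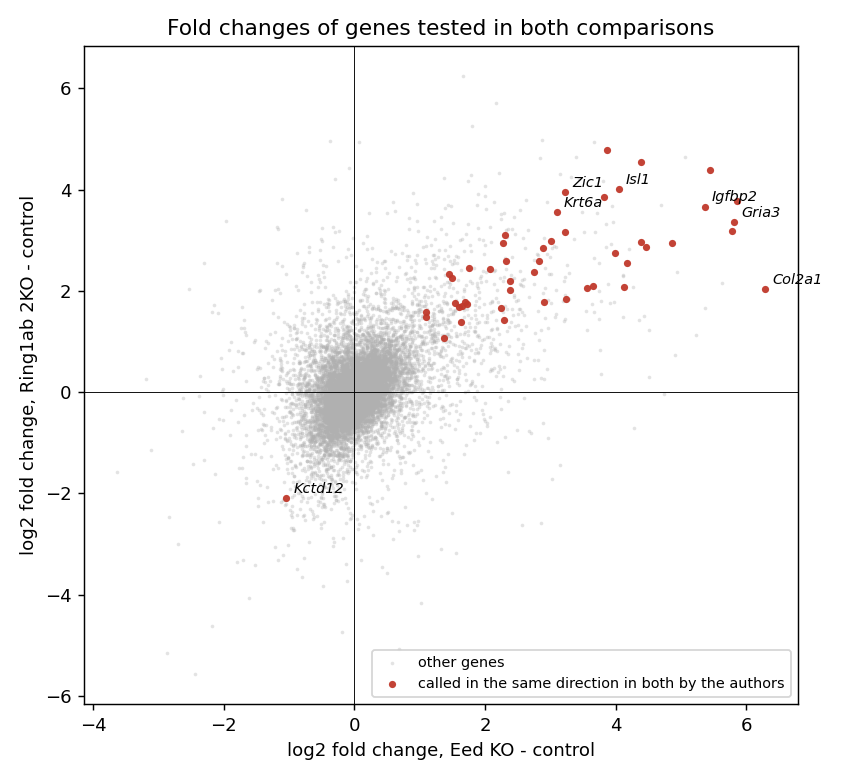
Log2 fold change of each gene in the Eed knockout (x axis) and the Ring1a/b 2KO (y axis), with the 48 genes called in the same direction in both by the authors in red. The 47 genes called higher lie in the upper right and Kctd12 in the lower left.

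Whether the effects of the knockouts differ was tested gene by gene. Among genes with a mean of at least 50 in both tables, Col2a1 had the smallest p for a larger log2 fold change in the Eed knockout, with a difference of log2 fold changes of 4.26 (SE 1.07, 95% interval 2.17 to 6.35), and Slc4a8, Susd4, Nrarp and Fn1 followed in that direction. Ugt1a6b, Cpa6, Defb1, Krt24 and Nrg1 had the smallest p in the opposite direction, and none of these passed the adjusted threshold. The limma interaction called 0 of 15096 genes, with 285 at an unadjusted p under 0.05 and a smallest adjusted p of 1. The 285 lie well under the share of 0.05 that chance alone would give. The test was thus conservative on these libraries, and 0 calls do not show that the effects are alike. A z test from the standard errors in the authors' deposited tables called 1 gene, Esr1, the estrogen receptor, higher in the Eed knockout by a difference of 3.62 (adjusted p = 0.00873); it was named after its values were seen.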

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

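The tests of cells like those of the controls in larger number, of Merkel cells in the sort and of Y-linked genes as a class were chosen only after the result was seen. The differences between knockouts were tested with camera on the limma interaction, as Eed minus Ring1a/b 2KO, over the 30 lists with enough measured members; all 6 that passed were lost with an estimated correlation.

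Melanocyte markers differed between the knockouts, with a median difference of −0.616 (adjusted p = 0.00536, and adjusted p = 0.199 with an estimated correlation), the larger rise being in the Ring1a/b 2KO. Larger numbers of melanocytes like those of the controls would have brought Tyrp1 along with Dct: the 2KO libraries held 187 and 27 Tyrp1 reads beside 264 and 28 Dct reads, so 50.3 Tyrp1 reads would be expected in the controls, which held 0 beside 49 and 22 Dct reads. Larger numbers alone would thus not account for Tyrp1, but the test covers that gene only and followed from its 0 control reads. By group means Dct, Pmel and Tyr were 3.44-, 2.59- and 2.49-fold higher in the 2KO, as larger numbers could give. These folds rest mostly on 2KO 1. In 2KO 2 the counts of Dct, Pmel and Tyr were 50.2, 30.5 and 30.5, against 36.6, 33.2 and 24.9 in control 2. Their limma adjusted p were 0.445, 0.597 and 0.563. Mlana, with 3 control reads, had a larger ratio of 20.1 (counting interval 6.5 to 101). Larger numbers therefore stay open for the list in the 2KO. In the Eed knockout, Dct, Tyr and Pmel had a median log2 fold change of −0.372. Mlana had 0 control reads there and at least 10.8-fold more in the knockouts, which argues against larger numbers as the cause of its rise. Melanocytes are not epithelial, so the EpCAM gate would remove most of them, and a change in their state or expression of these genes in keratinocytes stays open; the melanocyte list has 20 genes, 11 of them at a control mean of at least 5 in both tables and 2 in another list.

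Merkel cell markers differed as well, with a median difference of −0.957 (adjusted p = 0.0132, and adjusted p = 0.204 with an estimated correlation). Krt18 and Isl1 carried much of the rise, while Krt8, abundant in Merkel cells, had 0.521 and 0 in the Ring1 controls and 8.03 and 1.79 in the 2KO libraries. If Merkel cells had entered the sort, despite gates on high α6-integrin and Sca1, the other members would rise too; their median was 0.09 in the Eed knockout (upper quartile 1.28, 11 members) and 0.681 in the 2KO (upper quartile 1.40, 10 members). With so few reads on most members, Merkel cells in the sort cannot be told apart from expression of these genes in the keratinocytes. The list has 16 genes, of which 5 in the Eed controls and 6 in the Ring1 controls had a mean of at least 5, and 2 belong to another list.

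Laminins and other matrix genes differed by a median of 0.475 (adjusted p = 0.00177, and adjusted p = 0.204 with an estimated correlation). Basal keratinocyte genes differed by 0.321 (adjusted p = 0.00536, and adjusted p = 0.443 with an estimated correlation). Immediate early and heat shock genes differed by 0.725 (adjusted p = 0.00536, and adjusted p = 0.801 with an estimated correlation). Imprinted genes differed by −0.589 (adjusted p = 0.00177, and adjusted p = 0.199 with an estimated correlation).

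Both Ring1a/b 2KO libraries had low Y-linked counts and both controls high ones, with 4 of 4 Y-linked genes lower in the 2KO, so a Y-linked difference between the libraries runs with the genotype. The Eed libraries, where low and high levels occur in both groups, gave a test set before the result was seen. For 41 autosomal genes called lower in the 2KO, the median difference between low and high Y-linked libraries was 0.238. In the 2KO their median was −2.096, so as a group they did not fall with low Y-linked levels in the Eed libraries. That contrast rests on control 3, the only low control, and knockout 2, the only high knockout. Control 3 also had the most Flg2 and Lor of all Eed libraries (4188 and 3748), so the contrast cannot exclude a Y-linked cause. For 168 autosomal genes called higher the difference was 0.646 (interquartile range 1.235, upper quartile 1.374) against 2.275, so part of that rise may go with the Y-linked difference, and it cannot be told apart from the genotype for these genes. The sex of the animals stays open as a biological explanation that the labels do not give.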

How the results depend on the processing

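The edgeR runs, the Y-linked term and every DESeq2 run without a library or with a block were chosen only after the result was seen. For genes changed in the Eed knockout, where limma called 0 (762 at an unadjusted p under 0.05, edgeR 0), the count was 124 with the authors' p-values adjusted again, 127 with the authors' changes centred, 127 in the authors' deposited table, 127 by DESeq2, 10 in 1 fit over 10 libraries and 1 with the replicate block; leaving out each library gave 0 to 4. For the Ring1a/b 2KO, where limma called 6, the count was 10 with no filter, 3 at 0.01, 222 with p-values adjusted again, 248 with the authors' changes centred, 231 in the authors' table, 231 by DESeq2, 0 in 1 fit and 36 with the block; leaving out each library gave 0 to 565. The overlap of 0 became 46, 50, 48 and 48 under the same adjustments and 1 with the block, and 0 to 2 without each library. The difference test gave 1 gene by the z test. DESeq2's 127 Eed calls became 81 with the Y-linked term and 30 to 189 without each library, sharing 27 to 99 genes with the full set; its 231 Ring1 calls became 39 to 679, sharing 31 to 129, and 320 with the block (152 higher, 168 lower), and its 48 shared calls 11 to 61. The cause was not tested, except that a stricter threshold leaves fewer calls by construction.

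The 14 Eed lists became 9 with the Y-linked term, 9 to 15 without each library and 0 with an estimated correlation; the 14 Ring1 lists became 0 with it. Reversed were proliferation genes relative to other genes in the Eed knockout without knockout 1 (median 0.007, range without each library 0.007 to 0.579), and in the 2KO without 2KO 2 interferon genes (0.385, range −1.371 to 0.385) and immediate early genes (0.215, range −2.444 to 0.215); the cause was not tested. Of other list values, 627 kept their side in the Eed knockout, 12 passed newly and 68 were lost; in the 2KO these were 568, 3 and 22. For named genes they were 1051, 158 and 0, and 1168, 301 and 23. Targeted genes kept 0 calls under every alternative. The threshold on fold size gave no list value.

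Of the 10 splits of the 6 Eed libraries, too few for a share under 0.05, limma gave 0 for the real split and 10 for the highest other, so 10 of 10 gave as many. DESeq2 gave 127 for the real split and 1200 for controls 1 and 3 with knockout 3 against the rest, so 2 gave as many, which points to a structure of the samples; lists gave 14 and 11, so 1 did. Depth limits genes near 3 control reads and the Ring1 libraries with 7162907 and 6237389 reads.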

Other observations

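The tests of 1 comparison's calls in the other were chosen only after the result was seen, as were the genes named here. Beyond the genes already described, Fbln2, Hmga2 and Sulf2 were among the 47 called higher in both knockouts. Fbln2, a matrix fibulin, went from 53.2 ± 14.2 to 435 ± 245 (SD, n = 3) in the Eed libraries and from 62.4 ± 17.8 to 464 ± 173 (SD, n = 2) in the Ring1 libraries. Hmga2, a chromatin protein of fetal cells, went from 36.4 ± 17.0 to 246 ± 216 and from 30.8 ± 10.4 to 202 ± 110. Sulf2, a sulfatase acting on heparan sulfate, went from 303 ± 134 to 2370.2 ± 1208 and from 458 ± 80.7 to 1645 ± 742.

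Esr1, the estrogen receptor, had 202 ± 59.6 and 3648 ± 2535 (SD, n = 3) in the Eed libraries and 332 ± 58.1 and 486 ± 337 (SD, n = 2) in the Ring1 libraries.

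A hypothesis is that loss of either complex raises a common group of genes. Of the 118 genes called higher in the Eed knockout by the authors, 114 were tested in the Ring1 libraries. Those 114 had a median log2 fold change of 1.754 there, with 109 positive (camera p = 6.68e-44, p = 0.0478 with an estimated correlation, fry p = 0.0203). Of the 183 called higher in the 2KO, 174 were tested in the Eed libraries. Those 174 had a median of 1.639 there, with 168 positive (camera p = 4.93e-57, p = 0.0298 with an estimated correlation, fry p = 0.0303). The libraries of the tables are separate, so a common group may be raised in both. A cause common to both knockouts that is not the loss of repression, such as a response to injury, stays open. Low Y-linked levels also ran partly with the knockout in both tables. They occurred in Eed control 3, Eed knockouts 1 and 3 and both 2KO libraries. With the Y-linked term DESeq2 made 81 Eed calls, 48 of them shared with its calls without the term. Whether the Y-linked difference adds to the common group was not tested.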
